A study of Homo sapiens with 18 samples.

How the data were processed

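Total RNA from 18 samples of CL1-5(TO-ERα)#18 cells, 9 groups of 2, was labelled with biotin and hybridized to Illumina BeadChip arrays by the authors. The deposited intensity table gives, per the file headers, a mean signal and a detection p for 47323 probes on each array. The intensities are linear and, as deposited, not normalized between arrays, and no subtraction of background shows in them. The detection p-value of each probe was made by the authors before deposit and is a multiple of 1 fixed step, as for a rank among 770 negative control probes. The authors also deposited quantile-normalized linear intensities for 47308 of the probes, with array medians of 112.458 to 112.565 and the probe order of the same array's raw column. The software, its version and the chip on which each array lay are not given in the sources used here. The 18 samples were joined to their columns by the group code and replicate number in the sample titles.

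Raw intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by a normal-exponential model whose parameters were inferred from the detection p-values, with an offset of 16, followed by quantile normalization and log2. A probe was kept when its detection p was below 0.05 on both arrays of at least 1 group, which left 19237 probes and set aside, among others, 23311 that no array detected. Gene symbols came from the annotation table of the array, which gave 1 symbol for 30106 probes, several for 8 and none for 17209 of the probes. Of the kept probes 14411 had 1 symbol, 10980 symbols in all, and 4826 were tested without a name.

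Means of the 9 groups were fitted on all 18 arrays with limma, with 9 residual and 4.97 prior degrees of freedom, and comparisons were tested with its empirical Bayes step. P-values were adjusted by the Benjamini-Hochberg method over the kept probes of each comparison, and an adjusted p below 0.05 is called passing, rising or falling. There were 13 planned comparisons, being induction, TNFα in uninduced cells, in induced cells and the difference, estradiol in the same 3 forms, estradiol added to TNFα and its departure from the sum of both, smoke particulates in 3 forms, and smoke against estradiol. Induction under smoke, TNFα in estradiol-treated cells and separate control arrays for estradiol and smoke were added after the data were examined. TNFα, estradiol and smoke responses were compared between pairs of comparisons by correlation across probes, with the value for shared control arrays taken from simulation of unchanged groups.

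The 22 gene lists were fixed before the data were examined. They covered NF-κB targets, interferon-stimulated genes, MHC class I presentation, estrogen-induced genes, the aryl hydrocarbon receptor battery, NRF2 targets, the ATF4 and unfolded protein response, heat shock, metallothioneins, DNA replication, mitosis, p53 targets, epithelial genes, mesenchymal and matrix genes, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, immediate early genes, hematopoietic markers, stromal and endothelial markers, and receptors. Each gene was represented by its probe with the highest mean. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. The adjustment over the 286 planned tests of a list in a comparison was planned, while adjusting the lists of the 2 added comparisons on their own was chosen after the data were seen. No smallest list size was required.

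Genes to be named were chosen by a rule written beforehand. In each comparison these were the 8 largest passing rises and 8 largest falls of probes with 1 symbol and no overlap between the arrays of both groups, or 5 and 5 for differences between responses, up to 4 members of each list with the smallest p, and a fixed set of known target genes. The text describes some of the genes so chosen, and gives the other probes of a gene where these differed widely from the one named. For 1 item left out on purpose the result is not reported here. The main settings, the alternatives except those said to be added, the lists and the naming rule were chosen before the data were examined. Alternatives were no background correction, scaling to the 75th percentile, the authors' normalized values, no detection filter, only probes detected on all 18 arrays, only the compared groups in the fit, the replicate number as a block, trended and robust variance, and leaving out each array. Recovery of known changes was tested on simulated data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. The normalized table lacks 15 of the raw probes, so the alternative with those values had none for them.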

Results

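Transcript levels were measured on Illumina BeadChip arrays in CL1-5(TO-ERα)#18 cells, a clone of the human lung adenocarcinoma line CL1-5 that makes estrogen receptor α (ERα) when doxycycline is added. Of the 9 groups of 2 arrays, 4 held uninduced cells and 5 held cells induced with 1 µg/ml doxycycline for 24 h beforehand. Uninduced and induced cells alike received for 24 h either no further treatment, 45 U/ml of the inflammatory cytokine TNFα, 1 nM of the estrogen 17β-estradiol, or 20 µg/ml cigarette sidestream smoke particulates, and a ninth, induced group received estradiol together with TNFα. The design asked how ERα changes the TNFα response, how estradiol and TNFα act together, and how smoke particulates compare with estradiol. The ERα gene ESR1 has 1 probe on the array, which was detected on 2 of the 18 arrays at most and was not tested, so its reading does not check the doxycycline label. Probes for the estrogen targets PGR, GREB1, TFF1 and CXCL12, for CYP1A1, and for the cytokines CCL2 and IL6 were also too dim on these arrays to be tested.

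Median raw intensity per array lay between 104.586 and 124.347, and the replicate arrays of a group correlated across probes at 0.989 to 0.995, with the lowest value in uninduced cells given TNFα. The arrays fell into 2 sets, with each group whole in 1 of them. All 10 induced arrays lay in 1 set and 6 of the 8 uninduced ones made up the other, so the split largely followed doxycycline and cannot be separated from the groups. The 6 arrays of uninduced cells without treatment, with TNFα and with estradiol had maximum intensities of 27563.5 to 34389.9 and 16020 to 16381 detected probes, against 40177.8 to 45272.6 and 17327 to 18595 on the other 12, which included both arrays of uninduced cells given smoke particulates. Across the 23311 probes detected on no array, Spearman correlations between arrays were 0.772 to 0.796 within the 6, 0.752 to 0.797 within the 12 and 0.689 to 0.731 between the sets. The first principal component of the normalized values held 28.1% of the variance and the second 12.7%. Comparisons that cross the sets are named as such where they are given. P-values weigh differences against the spread between the 2 arrays within groups, which the labels call independent samples. They cover samples of this clone only, and the number of arrays limits the precision. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333. Single-gene differences therefore rest on limma's pooled estimate of the spread over all 18 arrays. Replicates of uninduced cells not given smoke differed more than the others. The SD of their log2 difference was 0.295 untreated, 0.323 with TNFα and 0.305 with estradiol, against 0.212 to 0.254 in the other groups. The pooled estimate may thus be too small for comparisons with these arrays.

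**Figure D1:**
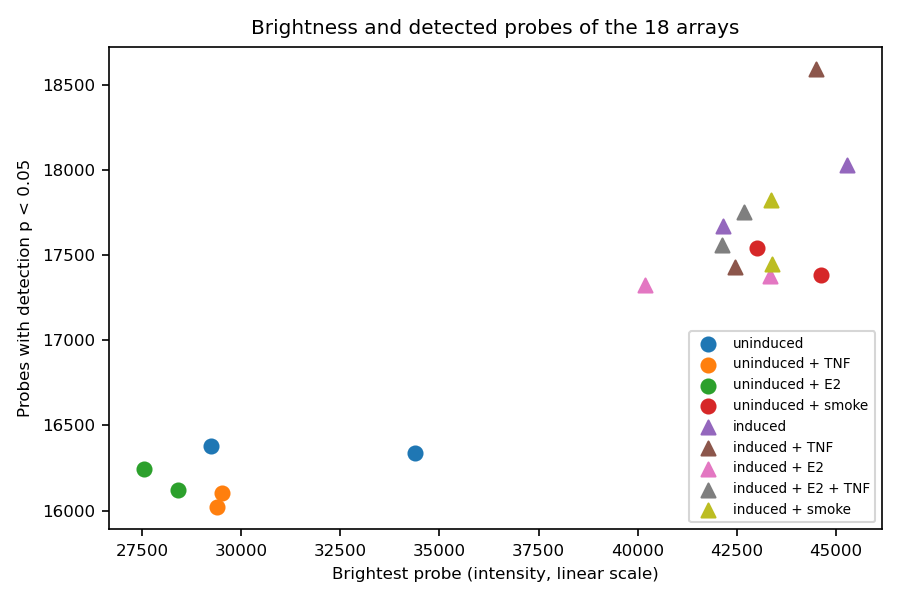
Detected probes against maximum raw intensity of each of the 18 arrays, by group. The 6 dimmer arrays had 16020 to 16381 detected probes and the other 12 had 17327 to 18595.

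Induction of ERα alone raised KRT19, an epithelial keratin, at least 2.56-fold, and THBD, the endothelial anticoagulant receptor thrombomodulin, at least 2.45-fold (limma, adjusted p = 0.000114 and 0.00224, n = 2 arrays per group). Each was not detected on either uninduced array, and such a bound sets the brighter group's mean against the lowest detected signal on the dimmer group's arrays, or the probe's own signal there where that was higher. The epithelial-mesenchymal transcription factor SNAI2 rose by 0.74 ± 0.12 on the log2 scale (SE, adjusted p = 0.0139), FHL2 by 0.68 ± 0.11 (adjusted p = 0.0103) and CEBPB by 0.49 ± 0.11 (adjusted p = 0.038). TGM2, a transglutaminase, rose at least 1.78-fold by 1 of its 3 probes (adjusted p = 0.000685), while the other 2 differed by 0.15 and 0.16. Among the probes lower in induced cells, MICB-DT was at least 1.99-fold lower, the epidermal cytokine gene IL36B at least 1.54-fold and GPR83 at least 1.64-fold, all below detection on both induced arrays (limma, adjusted p = 0.0169, 0.00605 and 0.0109). Under smoke, where both groups lie in 1 array set, these 3 differed by -0.43, 0.18 and 0.10 and did not pass. There 0 of the 103 lowered probes were called lower, with a median of -0.0213 against -0.779. Of the 175 raised ones 38 were called higher, with a median over all 175 of 0.0871 against 0.754. The comparison under smoke was added after the data were examined. The falls, and the raised probes not called again, are thus not established as effects of induction.

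No fixed gene list moved as a group with induction. Of 28 measured estrogen-induced genes, 1 rose (FHL2) and none fell. Among 25 DNA replication genes, the licensing factor CDC6 rose at least 1.41-fold and the checkpoint mediator CLSPN at least 1.17-fold, and the others did not pass. NRIP1, an estrogen-regulated corepressor, differed by 0.34 ± 0.16 (adjusted p = 0.345). In all, 278 of 19237 probes passed, 175 higher and 103 lower, with 10 and 13 of them changed at least 2-fold, and 0 passed when only the arrays of the compared groups were fitted. This comparison crosses the 2 array sets, with the uninduced arrays in the dimmer 6. Leaving out any 1 of the 4 arrays gave 13 to 140 probes, with 13 without the first induced array. Scaling to the 75th percentile in place of quantile normalization put the share of higher calls at 28.5% against 62.9%, so the balance of rises and falls is not fixed by these data.

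TNFα in uninduced cells raised the neutrophil chemokine CXCL8 at least 5.05-fold, RELB, a subunit of the inflammatory transcription factor NF-κB, at least 4.47-fold, and the cytokine IL32 at least 2.57-fold (limma, adjusted p = 1.01e-08, 3.62e-07 and 3.62e-07, n = 2 arrays per group). The NF-κB inhibitor NFKBIA rose by 2.04 ± 0.12, NFKB2 by 1.94 ± 0.16 and the surface marker CD83 by 1.77 ± 0.15 on the log2 scale. The calcium-binding protein S100A4 fell by 1.16 ± 0.13 and ID3, an inhibitor of differentiation factors, by 1.15 ± 0.16 (adjusted p = 0.00034 and 0.00304). A second CXCL8 probe, detected on 1 of the 2 control arrays, differed by 0.88 ± 0.33 and did not pass (adjusted p = 0.15).

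Of 27 measured NF-κB targets 14 rose and none fell (17 when adjusted over the list alone; camera, adjusted p = 9.82e-16, and 0.000634 with an estimated correlation). Of 14 genes of MHC class I antigen presentation 6 rose and 1 fell (10 and 1 over the list alone; adjusted p = 3.38e-07, and 0.00447 with an estimated correlation), the risers including the peptide transporter gene TAP1 by 0.82 ± 0.12, HLA-B by 0.93 ± 0.15 and TAPBP by 0.91 ± 0.16. HLA genes are near-identical in sequence, so which member a probe reads is uncertain. Interferon-stimulated genes rose as a group, 4 of 15 measured passing (5 higher and 1 lower when adjusted over the list alone; adjusted p = 0.00324, and 0.0408 with an estimated correlation), with the antiviral genes OAS3 at 0.89 ± 0.13 and IRF7 at 0.70 ± 0.15. Second probes of IRF7 and TAPBP differed by 0.34 and 0.56 and did not pass. The cell-cycle inhibitor CDKN1A rose by 0.84 ± 0.10 (adjusted p = 0.000912). Among the estrogen-induced genes IGFBP4 fell by 0.60 ± 0.14.

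A further 4 lists moved by the preset test alone. Cholesterol synthesis had 2 of 12 genes higher, INSIG1 by 0.93 ± 0.16 and HMGCS1 by 0.48 ± 0.11 (6 over the list alone; adjusted p = 0.000936, and adjusted p = 0.116 with an estimated correlation). Oxidative phosphorylation had 1 of 26 lower (5 over the list alone; 0.00065, and adjusted p = 0.0946 with an estimated correlation). Of the 25 replication genes 1 was higher (1 over the list alone; 0.0205, and adjusted p = 0.264 with an estimated correlation), and of 15 hypoxia and glycolysis genes 1 was higher, ALDOA by 0.53 ± 0.11 with a second probe at 0.21 not passing (4 over the list alone; 0.0372, and adjusted p = 0.25 with an estimated correlation). In all 609 probes passed limma's test, 266 higher and 343 lower, with 33 and 18 at least 2-fold, and 9 passed with only the compared groups in the fit. Under 75th-percentile scaling 25.2% of the calls were higher against 43.7%. Leaving out any 1 of the 4 arrays gave 111 to 1083 probes, with 1083 without the first array of the TNFα group and 111 without the second, so the count rests on these arrays.

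In induced cells the same dose of TNFα raised CXCL8 at least 25.5-fold and IL32 at least 4.38-fold (limma, adjusted p = 1.3e-11 and 2.09e-08, n = 2 arrays per group). A second CXCL8 probe rose less, by 2.71 on the log2 scale against 5.29 for the probe named, and passed. CST1, a cystatin protease inhibitor, rose at least 3.28-fold, the inflammasome sensor NLRP3 at least 3.04-fold and the leukocyte adhesion molecule ICAM1 at least 2.53-fold, each undetected on both arrays of induced cells without TNFα. Of 3 NLRP3 probes 2 passed and the dimmest differed by 0.36. RELB rose by 2.40 ± 0.15, CD83 by 2.32 ± 0.15 and NFKBIA by 2.16 ± 0.12. The adaptor SORBS2 fell by 1.67 ± 0.17, the insulin receptor substrate IRS1 by 1.33 ± 0.16, KRT80 by 1.07 ± 0.14 and ANGPT2 by 1.00 ± 0.12. KRT19 rose by a further 1.02 ± 0.13 and SNAI2 by 0.94 ± 0.12.

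NF-κB targets rose in 15 of 27 cases with no fall (18 when adjusted over the list alone; camera, adjusted p = 1.68e-41, and 2.2e-05 with an estimated correlation). MHC class I genes rose in 7 of 14 cases (10 over the list alone; adjusted p = 4.23e-16, and 0.000634 with an estimated correlation), the immunoproteasome subunit gene PSMB8 by 1.23 ± 0.17 and PSMB9 at least 1.79-fold. Of 4 PSMB8 probes 2 passed, and the others differed by 0.94 and 0.20. Interferon-stimulated genes rose in 4 of 15 cases (10 over the list alone; 4.55e-11, and 0.00236 with an estimated correlation). Of 6 genes of the metallothionein list 3 rose (3 over the list alone; 0.00167, and 0.0469 with an estimated correlation), MT2A by 1.30 ± 0.11, MT1G by 1.59 ± 0.21 and MT1X by 1.04 ± 0.17. The list holds metallothioneins, whose products bind zinc and copper, and the zinc transporter gene SLC30A1. Counts for metallothioneins in other comparisons are over this same list. The metallothionein genes too are near-identical, and the member read by each of their probes is uncertain. Immediate early genes rose in 3 of 15 cases (5 over the list alone; 6.53e-05, and 0.0149 with an estimated correlation), JUNB by 1.11 ± 0.17 and DUSP1 by 0.80 ± 0.12. FOSB, detected on 1 of the 2 control arrays, was 0.94 ± 0.19 higher (adjusted p = 0.0235). In all 190 probes passed, 147 higher and 43 lower, 66 and 8 of them at least 2-fold, and 102 to 119 passed without any 1 of the 4 arrays and 112 with only the compared groups in the fit.

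Whether the TNFα response itself differed with induction was tested as a difference of the differences. CXCL8 gained 2.19 ± 0.18 more log2 units in induced cells (limma, adjusted p = 0.000108, detected on 4 of the 8 arrays), while its second probe gave 1.83 ± 0.46 and did not pass (adjusted p = 0.14). CST1 gained 2.36 ± 0.14, NLRP3 2.07 ± 0.25 and ICAM1 1.97 ± 0.32, each detected on 2 of the 8 arrays, and these sizes depend on how undetected signal is normalized. Of 3 NLRP3 probes the dimmest differed by 0.33 and did not pass. Among genes detected on all 8, the proteoglycan SDC4 gained 1.10 ± 0.18, while the brighter probes of ANGPT2 (-0.86 ± 0.13) and DMBT1 (-1.05 ± 0.16) responded less or fell further. Their dimmer probes differed by -0.73 and -0.02 and did not pass (adjusted p = 0.0992 and 0.98). NFKBIA differed by 0.13 ± 0.17 and did not pass (adjusted p = 0.785).

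Of the NF-κB targets 3 gained more and none less (8 over the list alone; camera, adjusted p = 0.000896, and 0.0208 with an estimated correlation). Metallothioneins gained in 3 of 6 cases, MT1X by 1.46 ± 0.25 and MT1G by 1.66 ± 0.30 (4 over the list alone; 0.00449, and adjusted p = 0.0662 with an estimated correlation). By the preset test alone, with no member passing by itself, replication genes (0.00202, and adjusted p = 0.17 with an estimated correlation), hypoxia and glycolysis genes (3 lower over the list alone; 0.00162, and 0.0946) and cholesterol synthesis genes (2 lower over the list alone; 0.0278, and 0.261) responded lower in induced cells and oxidative phosphorylation genes higher (0.036, and 0.261). KRT19 gained 1.29 ± 0.18 (adjusted p = 0.0121), detected on 4 of the 8 arrays and on none of uninduced cells, so this size too depends on how undetected signal is normalized.

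In all 45 probes passed, 38 of them with the larger value in induced cells (84.4%, and 73.7% of 95 with the authors' normalized values). The uninduced arrays are among the dimmer 6 and the induced ones among the other 12. Each response was thus taken within a set, but the responses compared come from different sets. Whether the sets measure responses alike was not tested, so these calls cannot be separated from the split of the arrays. Leaving out any 1 of the 8 arrays gave 4 to 265 probes, with 265 without the first array of uninduced cells given TNFα and 4 without the first of induced cells given TNFα, and 4 passed with only the compared groups in the fit. Across all probes the responses of uninduced and induced cells correlated at r = 0.152 (rho = 0.036), with genes not being independent replicates. They shared 56 raised probes, against 2.03 for independent lists, 9 lowered ones against 0.767, and 1 called in opposite directions.

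**Figure D2:**
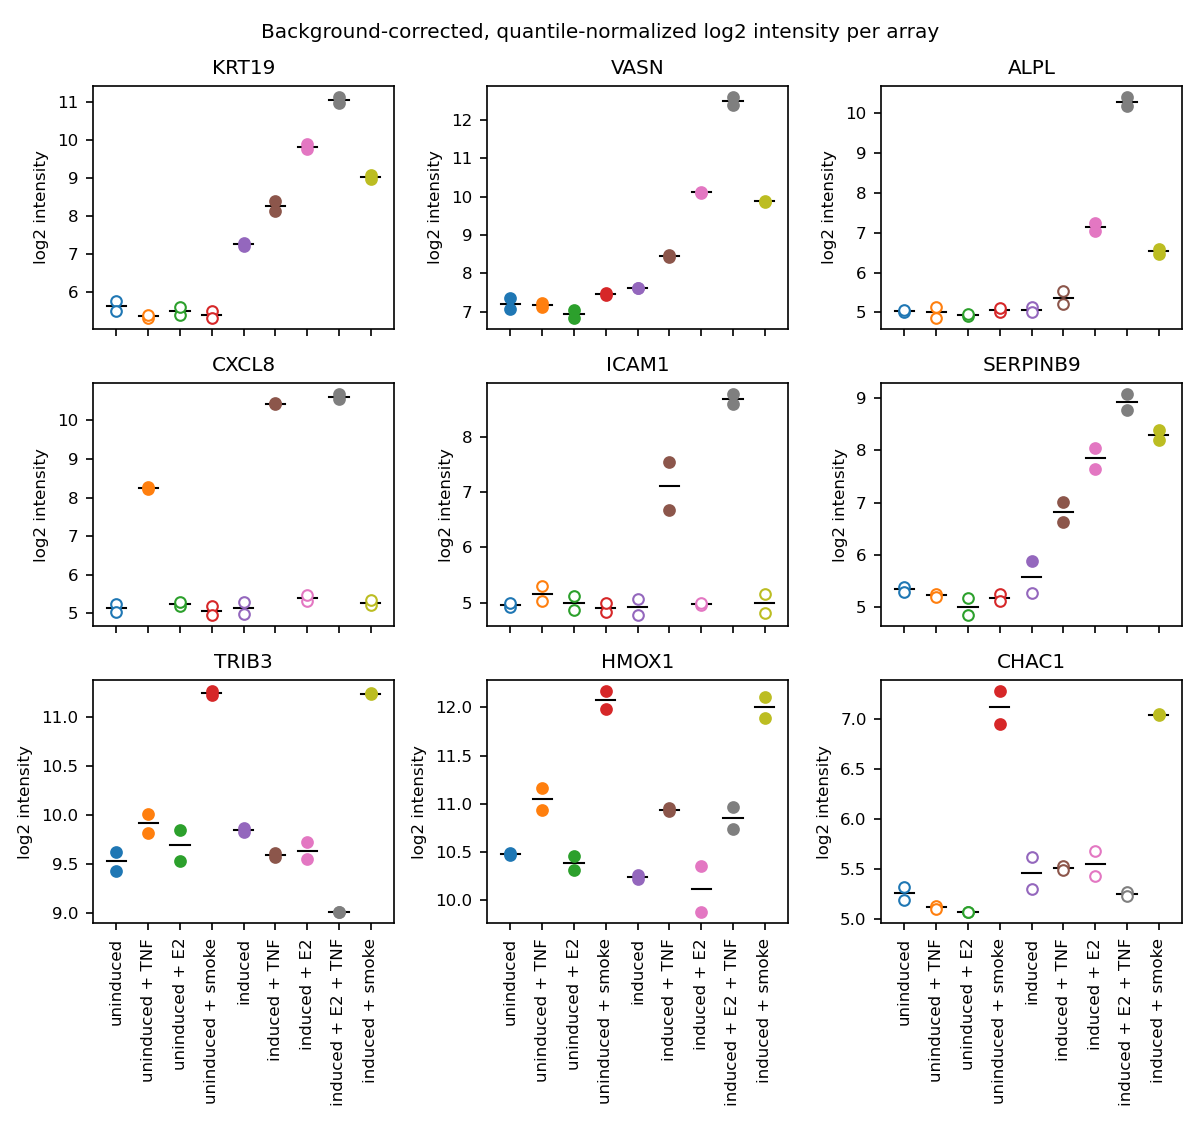
Normalized log2 intensity of 9 genes on each of the 18 arrays by group, with filled points detected, open points not detected and a line at each group's mean. The CXCL8 probe shown rose at least 5.05-fold with TNFα in uninduced and at least 25.5-fold in induced cells. A second CXCL8 probe, not shown, differed by 0.88 and 2.71 on the log2 scale. KRT19 rose by 2.58 with estradiol in induced cells.

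Estradiol in induced cells raised KRT19 by 2.58 ± 0.13, VASN by 2.49 ± 0.12 and TGM2 by 1.47 ± 0.11 on the log2 scale (limma, adjusted p = 8.34e-08, 4.59e-08 and 4.6e-06, n = 2 arrays per group). CST1 rose at least 3.63-fold, ALPL, the tissue-nonspecific alkaline phosphatase, at least 2.60-fold and the imprinted noncoding RNA H19 at least 1.71-fold. The brighter SERPINB9 probe, which 1 of the 2 control arrays detected, was 2.27 ± 0.20 higher, while the dimmer one differed by 0.64 and did not pass (adjusted p = 0.387). The other TGM2 probes differed by 0.81, which passed, and 0.49, which did not, and the cyclin gene CCNA1 rose by 1.42 ± 0.14. SORBS2 fell by 1.00 ± 0.17, the matrix protein gene THBS1 by 0.96 ± 0.18, IRS1 by 0.96 ± 0.16 and CCN2 by 0.68 ± 0.11, and 1 of 2 DMBT1 probes was at least 1.72-fold lower, with the other at -0.40 (adjusted p = 0.614).

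Of the 28 estrogen-induced genes 2 rose, FHL2 by 0.89 ± 0.11 and IGFBP4 by 0.76 ± 0.14, and none fell (7 when adjusted over the list alone; camera, adjusted p = 1.44e-06, and 0.00447 with an estimated correlation). Of the 12 cholesterol synthesis genes none passed, though the list was lower by the preset test (0.0201, and adjusted p = 0.255 with an estimated correlation). SDC4 rose by 0.82 ± 0.13, the interferon-stimulated exonuclease gene ISG20 by 0.78 ± 0.14 and SNAI2 by 0.68 ± 0.12. The proliferation genes CCND1 and MYC, often used as estrogen targets, differed by -0.02 ± 0.13 and, for the brighter MYC probe, 0.09 ± 0.14. In all 88 probes passed, 68 higher and 20 lower, 28 and 1 of them at least 2-fold, and 38 to 55 passed without any 1 of the 4 arrays and 11 with only the compared groups in the fit.

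In uninduced cells no probe passed with estradiol (limma, smallest adjusted p = 0.0626), with 2018 below an unadjusted p of 0.05, and no list moved. FHL2 differed by 0.22 ± 0.11 and IGFBP4 by -0.08 ± 0.14. The 68 probes that estradiol raised in induced cells had a median difference of -0.0108 here. Without background correction 1 probe passed, as higher, and with the authors' normalized values 1 did, also as higher, and 0 to 8 passed without any 1 of the 4 arrays, with 8 without the second estradiol array.

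The test of the difference between the 2 estradiol responses called VASN (2.77 ± 0.17, limma, adjusted p = 1.21e-06, detected on all 8 arrays), KRT19 (2.71 ± 0.18, on 4 of 8), SERPINB9 (2.60 ± 0.29, on 3 of 8), CST1 (2.49 ± 0.14) and ALPL (2.17 ± 0.19), both on 2 of 8, with the larger response in induced cells. All of these sizes but that of VASN depend on how undetected signal is normalized. The dimmer SERPINB9 probe differed by 0.53 and did not pass (adjusted p = 0.663). SDC4 differed by 1.07 ± 0.18, and ANGPT2 by -0.79 ± 0.13 on its brighter probe and by -0.73 on the other, which did not pass. No estrogen-induced gene passed by itself, 6 did when adjusted over the list alone, and the list responded more in induced cells (camera, adjusted p = 9.45e-05, and 0.0132 with an estimated correlation). In all 34 probes passed, 31 with the larger value in induced cells (91.2%, and 81.1% of 53 without background correction). The uninduced response comes from the dimmer array set and the induced one from the other. Whether the sets measure responses alike was not tested, so these calls cannot be separated from the split of the arrays. As for TNFα, each difference was taken within an array set, and 15 to 36 probes passed without any 1 of the 8 arrays, with 15 without the first array of induced cells given estradiol, and 6 with only the compared groups in the fit.

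Estradiol given together with TNFα, compared with TNFα alone in induced cells, raised ALPL at least 23.4-fold, CD24, a surface glycoprotein, at least 8.27-fold and the growth factor TGFA at least 4.82-fold (limma, adjusted p = 2.94e-11, 9.91e-11 and 1.46e-07, n = 2 arrays per group). VASN rose by 4.06 ± 0.12, CST1 by 3.87 ± 0.10, CXXC5 by 2.83 ± 0.23, KRT19 by 2.78 ± 0.13 and the creatine kinase gene CKB by 2.71 ± 0.13. ANGPT2 fell by 1.23 ± 0.09, the nucleoporin gene NUP210 by 1.14 ± 0.14 and PLAUR, the urokinase receptor gene, by 1.11 ± 0.12.

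Of the 28 estrogen-induced genes 11 rose and none fell (16 when adjusted over the list alone; camera, adjusted p = 1.93e-09, and 0.0024 with an estimated correlation), FOS by 1.92 ± 0.18 and IGFBP4 by 0.94 ± 0.14 among them. HSPB8 rose at least 3.44-fold, and the carbonic anhydrase gene CA12, detected on 1 of the 2 TNFα arrays, was 1.70 ± 0.13 higher. Metallothioneins rose in 4 of 6 cases (5 over the list alone; 1.82e-06, and 0.0116 with an estimated correlation), MT1F by 1.29 ± 0.18 and MT1X by 1.26 ± 0.17. Replication genes fell in 3 of 25 cases, TYMS, thymidylate synthase, by 0.50 ± 0.12 (11 over the list alone; 7.22e-07, and 0.0373 with an estimated correlation). Mitosis genes also fell in 3 of 25, CDC20 by 0.45 ± 0.12 and CCNA2 by 0.43 ± 0.11 (10 over the list alone; 1.15e-06, and 0.0286 with an estimated correlation). CDKN1A rose by 0.71 ± 0.10.

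A smaller set of lists moved by the preset test alone. Of 12 epithelial genes 4 rose and 1 fell (5 and 2 over the list alone; 0.0087, and adjusted p = 0.0662 with an estimated correlation), the risers including CDH1, E-cadherin, at least 1.46-fold and the desmosome gene DSP by 0.71 ± 0.13, and KRT18 falling. A second DSP probe differed by -0.04 and did not pass. Immediate early genes rose in 4 of 15 cases and fell in 1 (5 and 2 over the list alone; 0.0207, and adjusted p = 0.0946 with an estimated correlation), EGR1 by 1.17 ± 0.12. Cholesterol synthesis genes fell in 4 of 12 cases, INSIG1 by 0.86 ± 0.16 and SQLE by 0.55 ± 0.11 (7 over the list alone; 0.000709, and adjusted p = 0.107 with an estimated correlation). Heat shock genes fell in 1 of 12, HSPA1B by 0.50 ± 0.11 (3 over the list alone; 0.0421, and adjusted p = 0.261 with an estimated correlation). Among NF-κB targets 5 rose and 4 fell, with no shift of the list (adjusted p = 0.303). The complement gene C3 rose at least 1.45-fold and ICAM1 by 1.57 ± 0.22, while CXCL8 differed by 0.18 ± 0.13. The interferon-stimulated genes IFIT1 and MX1, each detected on 1 of the 2 arrays of the combination, were -1.02 ± 0.19 and -0.76 ± 0.15 from TNFα alone. LOX, a collagen cross-linking enzyme, rose at least 2.85-fold. In all 900 probes passed, 569 higher and 331 lower, 204 and 14 of them at least 2-fold, and 446 to 472 passed without any 1 of the 4 arrays. Of the 68 probes raised by estradiol without TNFα, 65 were raised here too, against 2.01 for independent lists, and 11 of the 20 lowered ones were lowered, against 0.344.

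Read the other way, TNFα in estradiol-treated induced cells, a comparison added after the data were examined, raised CXCL8 at least 27.9-fold, NLRP3 at least 7.32-fold and ICAM1 at least 7.31-fold (limma, adjusted p = 1.6e-11, 7.35e-08 and 1.23e-07). A second CXCL8 probe rose by 2.33 on the log2 scale against 5.21 for the probe named, and the dimmest of 3 NLRP3 probes by 0.80. CST1 rose by 3.73 ± 0.10, ALPL by 3.16 ± 0.14, MT1G by 2.63 ± 0.21 and CDKN1A by 1.39 ± 0.10, while the integrin gene ITGA6 fell by 1.25 ± 0.13 and SORBS2 by 1.37 ± 0.17. NF-κB targets rose in 17 of 27 cases (18 up and 2 down over the list alone; camera, adjusted p = 3.53e-19, and 0.000103 with an estimated correlation). MHC class I genes rose in 9 of 14 (10 over the list alone; 2.56e-10, and 0.0011), immediate early genes in 8 of 15 with 1 lower (8 and 1; 0.000149, and 0.00961) and estrogen-induced genes in 9 of 28 (11; 3.2e-05, and 0.00513), each second p being with an estimated correlation. Mitosis genes fell in 9 of 25 cases, CENPA by 0.65 ± 0.10 (14 over the list alone; 5.14e-09, and 0.00824 with an estimated correlation). Replication genes fell in 6 of 25 (9 over the list alone; 3.48e-05, and adjusted p = 0.0507 with an estimated correlation). In all 1550 probes passed, 888 higher and 662 lower (57.3% higher, and 43.4% under 75th-percentile scaling), and 603 to 1049 without any 1 of the 4 arrays, with 603 without the second array of cells given estradiol alone, and 924 with only the compared groups in the fit.

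Estradiol and TNFα together departed from the sum of their separate log2 effects on 131 probes, 119 above it and 12 below (limma). A sum of log2 effects is a product of fold changes, so additivity of intensities was not tested. CD24 lay 3.58 ± 0.17 above the sum (adjusted p = 7.6e-08, detected on 2 of the 8 arrays), ALPL 2.86 ± 0.19 (4 of 8) and LOX 1.68 ± 0.17 (2 of 8), sizes that depend on how undetected signal is normalized. CXXC5, detected on all 8, lay 1.84 ± 0.33 above by 1 of 2 probes, the other giving 1.61 (adjusted p = 0.0587), and EGR1 0.87 ± 0.17. Below the sum on all 8 were the TNF-family ligand gene CD70 (-1.34 ± 0.18) and PLAUR (-1.18 ± 0.17 on the brightest of 3 probes, with -0.92 passing and -0.77 not passing on the others). Of the estrogen-induced genes 4 lay above it (7 over the list alone; camera, adjusted p = 0.000261, and 0.0164 with an estimated correlation), and of the metallothioneins 1, MT1F by 1.34 ± 0.26 (4 over the list alone; 6.53e-05, and 0.0208). No mitosis gene passed by itself, yet the list lay below the sum (5.65e-07, and 0.0251 with an estimated correlation). By the preset test alone so did replication genes (0.000784, and adjusted p = 0.129 with an estimated correlation), while epithelial genes (1 of 12, CDH1, detected on 2 of the 8 arrays, 3 above and 1 below over the list alone; 0.0207, and adjusted p = 0.0951) and immediate early genes (2 of 15, 4 and 1 over the list alone; 0.0441, and adjusted p = 0.129) lay above. CXCL8 differed from the sum by -0.08 ± 0.18. Without any 1 of the 8 arrays 62 to 83 probes passed.

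Smoke particulates in uninduced cells raised genes of the amino acid and redox stress responses. CHAC1, which degrades glutathione, rose at least 2.31-fold, the cystine transporter gene SLC7A11 at least 3.09-fold and the stress sensor SESN2 at least 2.07-fold (limma, adjusted p = 9.16e-06, 0.000165 and 0.00239, n = 2 arrays per group). TRIB3 rose by 1.71 ± 0.12, the heme oxygenase gene HMOX1 by 1.60 ± 0.15, and PCK2, mitochondrial PEP carboxykinase, by 1.46 ± 0.10. DEPP1 fell by 1.31 ± 0.12, TMEM45A by 1.26 ± 0.16, the growth factor antagonist SPRY1 by 1.18 ± 0.18 and KISS1R, the kisspeptin receptor gene, by 1.07 ± 0.13.

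Of 20 genes of the ATF4 and unfolded protein response 13 rose and none fell (15 when adjusted over the list alone; camera, adjusted p = 1.28e-15, and 0.00258 with an estimated correlation), asparagine synthetase ASNS by 1.09 ± 0.11 among them. NRF2 targets, the antioxidant genes, rose in 5 of 22 cases (8 up and 1 down over the list alone; 6.53e-05, and 0.0208 with an estimated correlation), GCLM by 0.66 ± 0.10. Hypoxia and glycolysis genes fell in 7 of 15 (1 up and 9 down over the list alone; 1.77e-06, and 0.0208), the vasodilator peptide gene ADM by 0.67 ± 0.13 and hexokinase HK2 by 0.61 ± 0.12. Mitosis genes fell in 5 of 25 (13 over the list alone; 4.69e-10, and 0.0129), the spindle motor KIF11 by 0.72 ± 0.13, each second p being with an estimated correlation.

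By the preset test alone, p53 targets rose in 2 of 13 cases, the cytokine gene GDF15 at least 1.31-fold and CDKN1A by 0.83 ± 0.10 (3 over the list alone; 0.0196, and adjusted p = 0.126 with an estimated correlation), and metallothioneins in 1 of 6, MT1F by 1.00 ± 0.18 (3 over the list alone; 0.00866, and adjusted p = 0.0896). Replication genes were lower with 1 up and 1 down (1 and 2 over the list alone; 0.00691, and adjusted p = 0.226), and cholesterol synthesis genes higher with none passing (4 over the list alone; 0.0302, and adjusted p = 0.264). Of 6 genes of the aryl hydrocarbon receptor battery, which respond to combustion products, TIPARP rose by 0.51 ± 0.13, CYP1B1, detected on 1 of the 2 uninduced arrays, differed by 0.27 ± 0.23, and the list did not pass (adjusted p = 0.243). Estrogen-induced genes did not pass as a list (1 higher, SLC7A5; adjusted p = 0.194). In all 1020 probes passed, 619 higher and 401 lower, with 50 and 24 at least 2-fold, and 9 passed with only the compared groups in the fit. The comparison crosses the 2 array sets, with the smoke arrays in the brighter 12, and 259 to 518 probes passed without any 1 of the 4 arrays.

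In induced cells smoke particulates raised VASN by 2.26 ± 0.12, THBD by 1.93 ± 0.17, KRT19 by 1.78 ± 0.13, HMOX1 by 1.76 ± 0.15 and SNAI2 by 1.31 ± 0.12 (limma, adjusted p = 1.74e-07, 2.32e-05, 4.37e-06, 1.74e-05 and 3.66e-05, n = 2 arrays per group). CST1 rose at least 2.58-fold and ABLIM3 at least 2.88-fold, and SERPINB9 and SEL1L3, each detected on 1 of the 2 control arrays, were 2.71 ± 0.20 and 1.95 ± 0.15 higher, while the dimmer SERPINB9 probe differed by 0.71 and did not pass (adjusted p = 0.0907). KISS1R fell by 1.70 ± 0.13, IRS1 by 1.33 ± 0.16, SPRY1 by 1.31 ± 0.18 and SORBS2 by 1.20 ± 0.17, and the BMP antagonist NOG was at least 2.19-fold lower. Of 3 SPRY1 probes the dimmest differed by -0.22 and did not pass.

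Estrogen-induced genes rose in 9 of 28 cases with no fall (13 when adjusted over the list alone; camera, adjusted p = 1.51e-07, and 0.00335 with an estimated correlation), FHL2 by 0.96 ± 0.11, IGFBP4 by 0.87 ± 0.14 and the transcription factor XBP1 by 0.67 ± 0.13. ATF4 and unfolded protein response genes rose in 10 of 20 (15 over the list alone; 1.8e-14, and 0.0029), TRIB3 by 1.39 ± 0.12. NRF2 targets rose in 9 of 22 (11 over the list alone; 1.57e-08, and 0.00447), GCLC by 0.93 ± 0.12 and the brighter NQO1 probe by 0.60 ± 0.10, while its dimmer probe differed by 0.52 ± 0.29. Metallothioneins rose in 4 of 6 (4 over the list alone; 0.000432, and 0.0298), MT2A by 0.78 ± 0.11. Hypoxia and glycolysis genes fell in 6 of 15 (7 over the list alone; 1.77e-06, and 0.0208), ADM by 0.90 ± 0.13 and ANKRD37 by 0.78 ± 0.11. Replication genes fell in 1 of 25 (9 over the list alone; 4.57e-06, and 0.0498) and mitosis genes in 1 of 25 (1 over the list alone; 1.72e-05, and 0.047), each second p in this group being with an estimated correlation.

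The aryl hydrocarbon receptor battery rose in 3 of 6 cases, CYP1B1 by 1.34 ± 0.23, TIPARP by 0.93 ± 0.13 and NQO1 (3 over the list alone; 0.00324, and adjusted p = 0.214 with an estimated correlation). Also by the preset test alone, p53 targets rose in 4 of 13 (4 over the list alone; 0.0237, and adjusted p = 0.133), mesenchymal and matrix genes fell in 5 of 15 and rose in 1, SNAI2 (3 up and 6 down over the list alone; 0.0239, and adjusted p = 0.0978), and immediate early genes rose in 5 of 15 and fell in 1 (7 and 1 over the list alone; 0.0464, and adjusted p = 0.129). In all 631 probes passed, 368 higher and 263 lower, 71 and 26 at least 2-fold. Under 75th-percentile scaling 963 passed with 39.1% higher against 58.3%. Without any 1 of the 4 arrays 222 to 283 passed, and 348 with only the compared groups in the fit.

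The smoke response differed with induction for 121 probes, 82 of them with the larger value in induced cells (limma). VASN differed by 2.01 ± 0.17 and SNAI2 by 1.20 ± 0.18, both detected on all 8 arrays (adjusted p = 7.82e-05 and 0.0074), and EGR1 by 1.01 ± 0.17. KRT19 (2.00 ± 0.18, detected on 4 of 8), SERPINB9 (2.88 ± 0.29, 3 of 8) and CST1 (2.05 ± 0.14, 2 of 8) also responded more in induced cells, while the angiotensin receptor gene AGTR1 (-1.28 ± 0.19, 6 of 8) and 1 of 3 ABL2 probes (-1.19 ± 0.21, 7 of 8) went the other way. The other ABL2 probes differed by -0.36 and -0.39, the dimmer SERPINB9 probe by 0.45 and a second SNAI2 probe by 0.57, and none of these passed. Sizes for genes detected on fewer than 8 arrays depend on how undetected signal is normalized. No estrogen-induced gene passed by itself, 3 did over the list alone, and the list responded more in induced cells (camera, adjusted p = 0.000999, and 0.0209 with an estimated correlation). HMOX1 and TRIB3 differed by 0.16 ± 0.22 and -0.32 ± 0.17 and did not pass (adjusted p = 0.815 and 0.442). The uninduced side of this difference crosses the array sets. Without any 1 of the 8 arrays 29 to 55 probes passed, and 21 with only the compared groups in the fit.

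**Figure D3:**
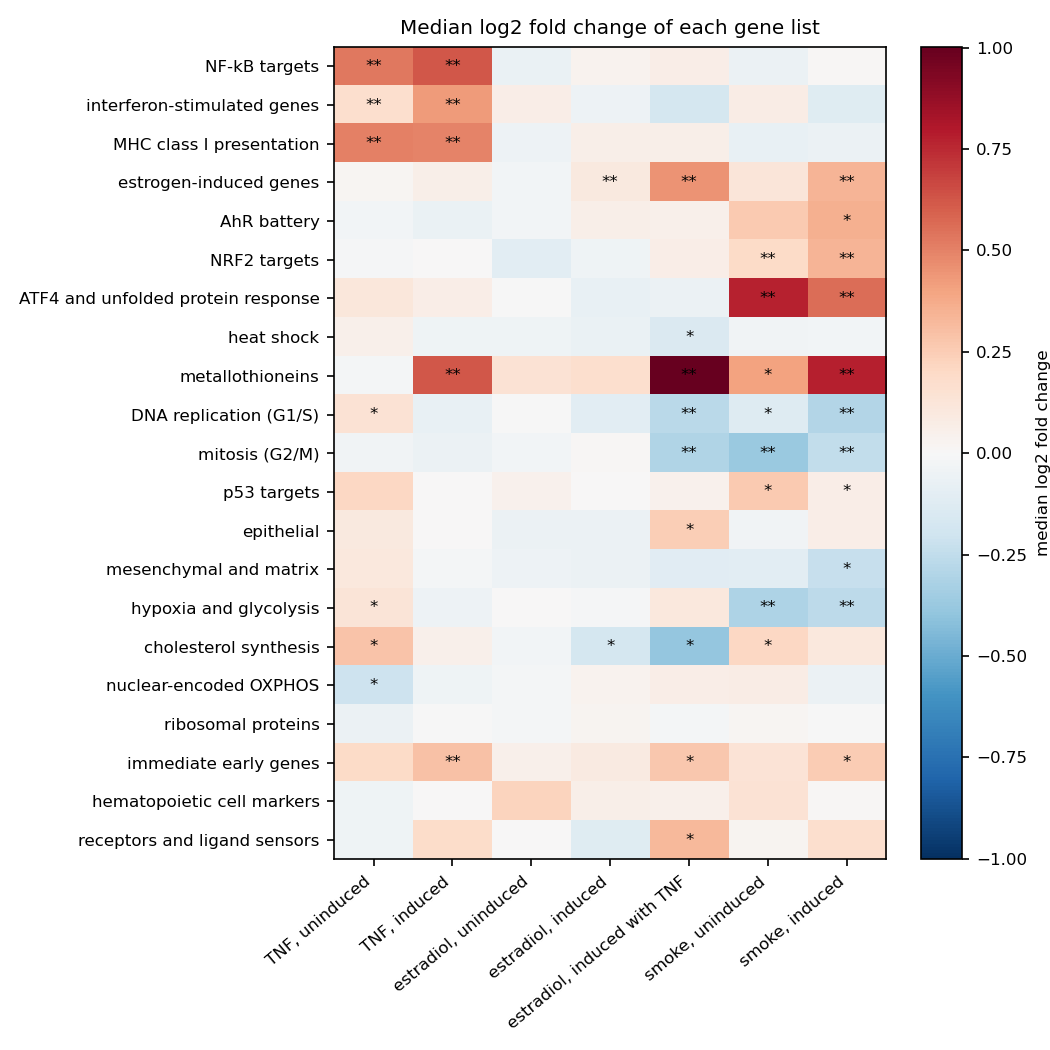
Median log2 fold change of 21 fixed gene lists in 7 comparisons, with * for a list that passed camera's preset test and ** for one that also passed with an estimated correlation. Under smoke in uninduced cells ATF4 and unfolded protein response genes had a median of 0.77 and mitosis genes of -0.37.

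Set directly against estradiol in induced cells, smoke particulates gave higher HMOX1 (1.89 ± 0.15), TRIB3 (1.60 ± 0.12), PCK2 (1.59 ± 0.10) and SLC7A11 (1.29 ± 0.17), and NIBAN1 was at least 1.98-fold higher (limma, adjusted p = 2.56e-05, 2.13e-05, 5.53e-06, 0.00132 and 5.14e-05, n = 2 arrays per group). With smoke KISS1R was lower by a difference of -1.50 ± 0.13, SPRY1 by -1.21 ± 0.15, KRT19 by -0.80 ± 0.13 and PLAUR by -0.83 ± 0.12. The dimmest of 3 SPRY1 probes differed by -0.07 and 1 of 3 PCK2 probes by 0.78, and neither passed. ATF4 and unfolded protein response genes were higher in 12 of 20 cases (15 when adjusted over the list alone; camera, adjusted p = 3.28e-14, and 0.0029 with an estimated correlation) and NRF2 targets in 9 of 22 (10 up and 1 down over the list alone; 1.82e-08, and 0.00447). Hypoxia and glycolysis genes were lower in 4 of 15 (8 over the list alone; 1.86e-06, and 0.0208) and mitosis genes in 2 of 25 (5 over the list alone; 7.69e-06, and 0.0408), again with the second p from an estimated correlation. Estrogen-induced genes were higher in 3 of 28 with no shift of the list (adjusted p = 0.194).

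By the preset test alone, smoke also gave higher values than estradiol for metallothioneins (2 of 6, 3 over the list alone; 0.0159, and adjusted p = 0.104 with an estimated correlation), cholesterol synthesis genes (2 of 12, 3 over the list alone; 0.0116, and adjusted p = 0.226), p53 targets (2 of 13, 2 over the list alone; 0.021, and adjusted p = 0.129) and the aryl hydrocarbon receptor battery (1 of 6, NQO1, 4 over the list alone; 0.00691, and adjusted p = 0.25). Replication genes were lower with none passing (2 over the list alone; 0.00435, and adjusted p = 0.208). The brighter MCM7 and PCNA probes, used for the list, differed by -0.18 and -0.06 and did not pass, while a dimmer probe of each gave -1.17 ± 0.16 and -1.07 ± 0.15 and passed. In all 583 probes passed, 316 higher with smoke and 267 lower (54.2% higher, and 32.6% of 1074 under 75th-percentile scaling). Without any 1 of the 4 arrays 80 to 359 passed, with 80 without the second estradiol array and 359 without the first, and 138 with only the compared groups in the fit.

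Both treatments of induced cells were compared with the same 2 control arrays, which alone gives their fold changes a correlation. Across probes r was 0.385 (rho = 0.284), while simulated unchanged groups gave 0.5 (0.484 to 0.518). The covariance was 0.0207 against a simulated 0.0147, a difference of 0.00595. Of the 68 probes raised by estradiol, 59 were among the 368 raised by smoke, against 1.30 for independent lists, and 13 of the 20 lowered were among the 263 lowered, against 0.273, with 0 in opposite directions. Sharing arrays by itself raises such counts. With 1 control array for each treatment and none shared, a test added after the data were examined, r fell to 0.0755 or 0.161 depending on which array served which treatment. The overlap of raised probes stayed, with 31 of 40 probes raised by estradiol also raised by smoke (0.318 for independent lists) in the first case and 32 of 35 (0.273) in the second, and 3 of 9 and 3 of 3 lowered. Single control arrays are noisier, which lowers r by itself, and that was not separated from the loss of the shared arrays. The shared genes included KRT19, VASN, SERPINB9, CST1, TGM2, FHL2 and IGFBP4 among those raised, and IRS1, SORBS2, THBS1, CCN2, ANGPT2, EDN1 and KRT80 among those lowered. Smoke in induced cells and estradiol in TNFα-treated cells share no array, and there r was 0.401 against a simulated -0.00121, with 170 probes raised in both against 10.9 for independent lists, 74 lowered in both against 4.53, and 11 in opposite directions. Smoke responses in uninduced and induced cells, which share no array either, correlated at 0.261, with 123 raised in both (11.8 for independent lists) and 66 lowered in both (5.48).

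**Figure D4:**
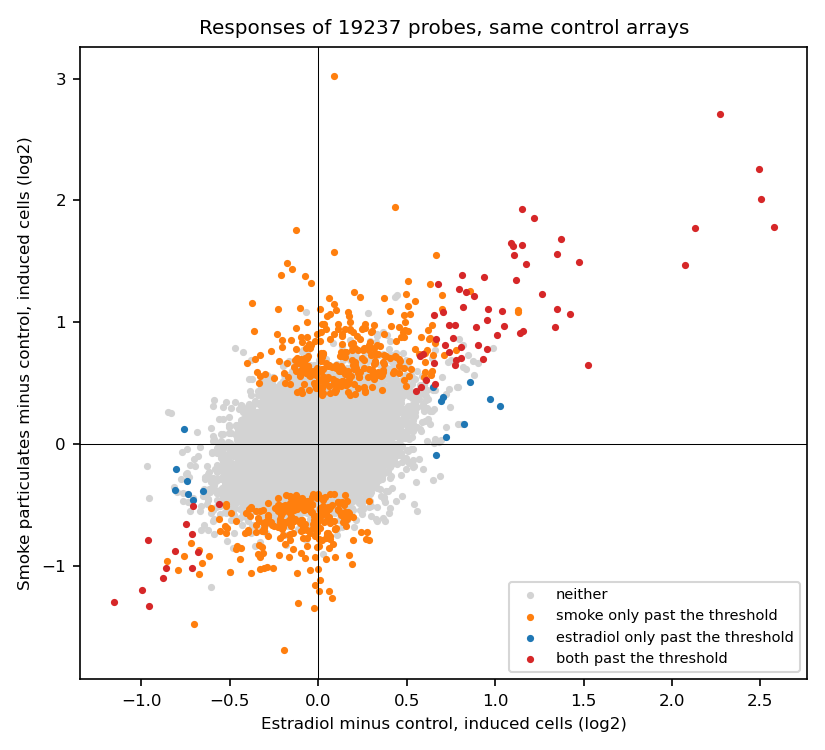
Log2 fold change of each tested probe with estradiol and with smoke particulates in induced cells, against the same 2 control arrays. Of 68 probes raised by estradiol 59 were raised by smoke too, and HMOX1 differed between the treatments by 1.89.

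The remaining lists bear on sample makeup and general state. Ribosomal protein genes did not move as a list in any of the 13 planned comparisons (22 measured, smallest adjusted p = 0.159). Of 13 hematopoietic cell markers 4 were measured, and that list did not pass either (smallest adjusted p = 0.254), although HBA1, detected on 1 of the 2 TNFα arrays, was 1.44 higher when estradiol was added. Of 10 stromal and endothelial markers only the tight junction gene CLDN5 was measured, so its result is that of 1 gene, and it rose at least 4.15-fold when estradiol was added to TNFα and lay 2.42 above the sum of the single treatments. Of 4 measured receptors the TNF receptor genes TNFRSF1B and TNFRSF1A rose, at least 1.51-fold and by 0.56 ± 0.14, when estradiol was added to TNFα (2 over the list alone; camera, adjusted p = 0.0297, and adjusted p = 0.171 with an estimated correlation), with 1 above the sum of the single treatments (1 over the list alone; 0.00821, and adjusted p = 0.104). Over all 13 planned comparisons 68 of 286 list tests passed with camera's preset correlation, 36 of them with an estimated one, and 111 with fry, which asks only whether a list's own genes move one way.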

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

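The tests of a separate technical set of arrays and of doxycycline as the cause of the array sets were chosen after that split was seen. The comparison of induced with uninduced cells under smoke, the correlation of smoke with estradiol responses that share no array, and the split of the control arrays were also chosen after the results they bear on were seen.

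Responses differed with induction or with the second treatment in 4 tests. For TNFα 45 probes passed, led by CST1 (2.36), CXCL8 (2.19), NLRP3 (2.07) and ICAM1 (1.97) in the direction of a larger value in induced cells, and CNN2 (-1.12), DMBT1 (-1.05), ANGPT2 (-0.86) and TSPAN33 (-0.82) in the other. A second probe did not pass for CXCL8 (1.83), CNN2 (-0.45, the far brighter of its probes), DMBT1 (-0.02) or ANGPT2 (-0.73), and 1 of 3 did not for NLRP3 (0.33). For estradiol 34 probes passed, led by VASN (2.77), KRT19 (2.71), SERPINB9 (2.60), CST1 (2.49) and ALPL (2.17), with ANGPT2 (-0.79) in the other direction, while second probes of SERPINB9 (0.53) and ANGPT2 (-0.73) did not pass. For smoke particulates 121 passed, led by SERPINB9 (2.88), CST1 (2.05), VASN (2.01), KRT19 (2.00) and ABLIM3 (1.63), with AGTR1 (-1.28), SLC16A7 (-1.21), PAEP (-1.21), ABL2 (-1.19) and DMBT1 (-1.14) the other way. Other probes did not pass for SERPINB9 (0.45), PAEP (-0.09), ABL2 (-0.36 and -0.39) and DMBT1 (-0.31). The uninduced side of the smoke test crosses the array sets, so how many of the 121 come from the treatment stays open. The TNFα and estradiol tests by induction compare responses from different sets, and whether the sets measure responses alike was not tested. For estradiol with TNFα 131 departed from the sum of both, led by CD24 (3.58), ALPL (2.86), CLDN5 (2.42), TMOD1 (2.15) and SLCO2B1 (2.12) above it, and CD70 (-1.34), PLAUR (-1.18), ULK3 (-1.05), EOLA2 (-1.04) and BAIAP2L2 (-1.001) below. CD24, CLDN5 and TMOD1 were detected on 2 of the 8 arrays and ALPL, SLCO2B1 and ULK3 on 4, so their sizes and order rest partly on undetected signal. The same holds for CST1, CXCL8, NLRP3 and ICAM1 under TNFα, for KRT19, SERPINB9, CST1 and ALPL under estradiol, and under smoke for all the genes given but VASN. A brighter EOLA2 probe differed by 0.04 and did not pass.

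The uninduced arrays other than those with smoke stood apart from the other 12, and 278 probes were called between induced and uninduced cells across that split. Over never-detected probes the lowest correlation within a set exceeded the highest between sets by 0.0214, as a separate chip or run would give. The uninduced smoke arrays correlated less with the 6 uninduced arrays than with the induced ones, by a difference of -0.0624, which argues, by this 1 group alone, against doxycycline as the cause of the split. Of the 278 calls 38 (13.7%), all of them rises and 0 of the 103 falls, were called the same way under smoke within the 12 arrays, where the median change in their direction was 0.0692 against 0.766, so the split of the arrays may account for much of the induction result. The same split lies under smoke in uninduced cells, where 189 of 1020 calls (18.5%) were also made in induced cells. The median change in their direction was 0.154 there against 0.665. Of the 278 induction calls 167 (60.1%) were called the same way by smoke in uninduced cells, with a median of 0.616. Both comparisons cross the sets and share the untreated uninduced arrays, and these were not separated. Which induction and smoke calls come from the treatments stays open.

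With estradiol and TNFα together, 131 probes departed from the sum of the log2 effects of the single treatments, 119 above it and 12 below. Signal below background in the single treatments cannot be the cause for the 60 of 131 probes (45.8%) detected on all 8 arrays, 52 of them above the sum. It stays open for the others, 44 of which were detected in the combination alone. Under 3 other scalings at least 126 probes passed, so the count did not rest on the main scaling. The authors' values, among these scalings, were quantile-normalized too, and only counts were compared, not the probes. The counts thus do not decide whether normalization between arrays is a cause. A joint action of both treatments on those 60 probes could be a hypothesis, found and tested on the same data, with normalization left open.

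Smoke and estradiol raised some of the same genes in induced cells, 59 of the 68 probes raised by estradiol and of the 368 raised by smoke. Of those 368 probes, 164 were called higher with smoke than with estradiol, so much of the smoke response was not shared. Smoke responses and those to estradiol under TNFα, which share no array, correlated at 0.401, and with separate control arrays 31 of 40 probes raised by estradiol (32 of 35 with the controls exchanged) were also raised by smoke, which argues against shared control arrays as the whole cause, although the correlation of both responses across all probes then fell from 0.385 to 0.0755 or 0.161. Probes raised by estradiol were higher in induced than in uninduced cells under smoke, with a median difference of 1.14 (quartiles 0.843 to 1.44), which argues against a smoke response that needs no induction. Of the 68 probes raised by estradiol, TNFα in induced cells raised 30, with a median change of 0.473 against 0.970 for smoke. In uninduced cells these medians were -0.000964 for TNFα and 0.0503 for smoke. A rise of these probes in induced cells alone is thus not particular to smoke. The TNFα, smoke and estradiol comparisons in induced cells share the same control arrays. An action of smoke particulates through the induced receptor is a hypothesis that the smoke values allow, found and tested on the same data. Whether doxycycline without the receptor would do the same was not tested, since no such cells are in the design.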

How the results depend on the processing

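The alternatives of induction under smoke, TNFα in estradiol-treated cells, the correlation without shared arrays and the separate control arrays were chosen after the data were examined. No Pearson correlation and no passing result for a named gene changed sign. The balance of higher and lower calls did turn under 75th-percentile scaling, from 62.9% to 28.5% higher for induction, 58.3% to 39.1% for smoke in induced cells, 54.2% to 32.6% for smoke against estradiol and 57.3% to 43.4% for TNFα in estradiol-treated cells. With probes detected on all 18 arrays the last 3 were 48.3%, 49.6% and 47.5%, and estradiol added to TNFα went from 63.2% to 49.9%. For TNFα in uninduced cells, 43.7% higher, it turned in the fit of the compared groups (100%) and without the second array of either group (63.5% and 54.1%). Comparing induced with uninduced cells under smoke, on all kept probes and in place of untreated cells, gave 844 against 278. Counts are of passing probes, and the cause of a shift was not tested unless given. Groups left with 1 array assume that the lone array varies like the other groups, and chip as a block was not run since chip identities are not given in the sources used here.

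Fitting only the compared groups leaves fewer arrays for the spread. It gave 0 for induction, 9 for TNFα in uninduced cells, 112 for TNFα in induced cells and 4 for the difference of those responses. For estradiol it gave 11 in induced cells and 6 for the difference by induction. For smoke it gave 9 in uninduced cells, 348 in induced cells and 21 for the difference. Smoke against estradiol gave 138 and TNFα in estradiol-treated cells 924. Replicates differed more in uninduced cells not given smoke than in the other groups. A spread pooled over all 18 arrays may thus be too small for comparisons with those cells. With only probes detected on all 18 arrays, which removes those detected in some groups, induction gave 22, the TNFα difference 23, estradiol in uninduced cells 3, the estradiol difference 19, the departure from the sum of TNFα and estradiol 52, smoke in uninduced cells 625 and the smoke difference 57.

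Without background correction TNFα in uninduced cells gave 992, its difference by induction 87, estradiol in uninduced cells 1, the estradiol difference 53 and smoke against estradiol 948. The authors' values gave 1044, 95, 1, 55 and 987 for the same results. Scaling to the 75th percentile gave 963 for smoke in induced cells and 1074 for smoke against estradiol. Trended and robust variance gave 1157 for TNFα in uninduced cells, 130 for its difference and 1099 for smoke against estradiol. Without a detection filter TNFα in uninduced cells gave 380 and its difference 28. The correlation of TNFα responses, 0.152, was 0.181 with 75th-percentile scaling, 0.101 without the filter and 0.134 with probes detected everywhere. The correlation of smoke and estradiol responses without shared arrays, 0.401, was 0.434 without background correction, 0.386 with 75th-percentile scaling, 0.436 with the authors' values, 0.307 without the filter and 0.432 with probes detected everywhere. The correlation of estradiol and smoke responses in induced cells, 0.385, was 0.0755 with separate control arrays when estradiol was set against the first and 0.161 when against the second, and Spearman's rho, 0.284, was -0.0195 and 0.0911. Of 68 passing list tests 36 passed with an estimated correlation, and fry gave 111.

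Without any 1 array the lowest and highest values were 13 and 140 for induction, 111 and 1083 for TNFα in uninduced cells, 102 and 119 in induced cells, 4 and 265 for the difference, 38 and 55 for estradiol in induced cells, 0 and 8 in uninduced cells, 15 and 36 for the difference, 446 and 472 for estradiol added to TNFα, 62 and 83 for the departure from the sum, 259 and 518 for smoke in uninduced cells, 222 and 283 in induced cells, 29 and 55 for the difference, 80 and 359 for smoke against estradiol, and 603 and 1049 for TNFα in estradiol-treated cells. Correlations were 0.256 to 0.520 for estradiol and smoke, 0.109 to 0.159 for TNFα and 0.359 to 0.389 without shared arrays.

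With the replicate number as a replicate block, counts in the order of the planned comparisons were 269 for induction, 627, 185 and 35 for TNFα in uninduced and induced cells and the difference, 88, 0 and 30 for estradiol, 912 for estradiol added to TNFα, 111 for the departure from the sum, 975, 618 and 107 for smoke, 584 for smoke against estradiol, and 1548 for TNFα in estradiol-treated cells. Differences between the first and second array of a group correlated across probes at -0.105 to 0.132 over 36 pairs of groups (median 0.0185), with 3 above 0.1, so the numbers do not pair the samples. Of the 467 passing results for named genes, 256 passed again with only the compared groups in the fit and 211 did not. Without a detection filter 51 of the 467 did not pass, under 75th-percentile scaling 38 and with the authors' values 19. Leaving out single arrays also removed some of these calls.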

Other observations

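The 2 comparisons described first here were added after the data were examined.

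Induced cells were also compared with uninduced cells under smoke particulates, where both groups lie within the 12 brighter arrays, a comparison added after the data were examined. KRT19 was at least 9.47-fold higher in induced cells and 1 of 3 TGM2 probes at least 5.40-fold (limma, adjusted p = 2.39e-09 and 9.07e-09). THBD rose by 2.45 ± 0.17, VASN, a TGF-β-binding membrane protein, by 2.42 ± 0.12, and SNAI2 by 1.94 ± 0.12. The serpin SERPINB9, an inhibitor of granzyme B, was at least 5.62-fold higher by its brighter probe, while the other differed by 0.55 and did not pass (adjusted p = 0.156). The other TGM2 probes, of which 1 was brighter, rose by 0.98 and 0.62. WNT5B fell by 1.23 ± 0.11, the angiopoietin gene ANGPT2 by 1.01 ± 0.09 and the matricellular gene CCN2 by 0.86 ± 0.11 (n = 2 arrays per group). Of the 28 estrogen-induced genes, 8 were higher and none lower (10 when adjusted over the list alone), FHL2 by 1.37 ± 0.11 and the growth factor binding protein IGFBP4 by 1.02 ± 0.14 among them, and the list was higher as a group (camera, adjusted p = 1.25e-05, and 0.00513 with an estimated correlation). Of 12 cholesterol synthesis genes 1 was lower, MVK, by a difference of -0.81 ± 0.15, and the list was lower by the preset test alone (adjusted p = 0.0434, and adjusted p = 0.282 with an estimated correlation). The comparison called 844 probes, 537 higher and 307 lower. Of the 175 probes raised by induction without smoke, 38 were also higher here, against 4.89 for independent lists, while none of the 103 lowered probes was lower here.

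TNFα given to estradiol-treated induced cells moved further lists than those described with that comparison. Metallothioneins rose in 4 of 6 cases, MT2A by 1.68 ± 0.11 and MT1X by 1.76 ± 0.17 (5 when adjusted over the list alone; camera, adjusted p = 1.57e-06, and 0.00513 with an estimated correlation), and interferon-stimulated genes in 2 of 15 (7 over the list alone; 0.00209, and 0.0229 with an estimated correlation). By the preset test alone, epithelial genes rose in 5 of 12 cases and fell in 1 (6 and 2 over the list alone; 0.0142, and adjusted p = 0.0558 with an estimated correlation), p53 targets rose in 3 of 13 (3 over the list alone; 0.0481, and adjusted p = 0.162), receptors rose in 2 of 4 (3 over the list alone; 0.0109, and adjusted p = 0.0815), and heat shock genes were lower with none passing (0.0266, and adjusted p = 0.192). HSPB8 rose at least 3.31-fold, LOX at least 2.75-fold and the drug transporter gene ABCC3 at least 2.32-fold, and FOSB rose by 2.06 ± 0.19 (limma, n = 2 arrays per group).

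The fit was tested on simulated data with the spread of these arrays and 200 changed probes in each of 5 draws. For a comparison of 2 groups, 1.6% of changes of 0.5, 93% of changes of 1 and 100% of changes of 2 log2 units were called, with false calls making up 0%, 5.87% and 6.19% of all calls. For a difference between responses the shares were 0%, 56% and 99.6%. With nothing changed, 1 probe was called in total over 5 draws. The simulated noise had the same spread in every group and no difference between the array sets. These shares therefore do not cover comparisons that cross the sets or use the dimmer arrays, whose replicates differed more. Changes of 0.5 were thus rarely called, so a probe that did not pass is not shown to be unchanged.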
